A study of Homo sapiens with 6 samples.

How the data were processed

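The series holds 6 arrays of the MR-EAhy human endothelial cell line, 3 without and 3 with 1 nM aldosterone for 6 h, after 24 h in 0.2% charcoal-treated serum. Groups and replicate numbers were taken from the labels. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted, amplified and labelled with Cy3 for 1-colour hybridization. Per the submitters' processing notes and the file headers, spots were quantified with Agilent Feature Extraction 9.5.3.1.

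The deposited scanner files hold a linear fluorescence intensity per spot, which is the processed signal after background correction by Feature Extraction, per the file headers, beside the raw mean signal and the median background. The authors' deposited value table holds a linear ratio with no recorded definition. Set against the scanner files, each of its columns equalled the processed signal divided by about that array's 75th percentile, with column medians of 0.0942, 0.0945 and 0.0941 for untreated replicates 1 to 3 and 0.0947, 0.102 and 0.102 for treated replicates 1 to 3. It was thus linear, without centring of genes, and how it was computed is not given in the sources used here.

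Control spots and spots with an outlier flag were left out, replicate spots of a probe were averaged, and the log2 processed signal minus the array's 75th percentile was the value used. No pseudocount was added. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 26662 of 41000 probes. Probes were named by matching the transcript accession in the files, without its version, to a RefSeq gene table (GRCh38.p14), used for names only. The main accession named 23958 probes, another RefSeq accession of the probe 338, a current symbol 2496 and an older symbol 985, and 13223 remained unnamed. A gene was represented by its kept probe with the highest mean over the 6 arrays, and unnamed probes were tested on their own. Among 51 called genes with other kept probes, 67 of the 69 other probes had the same sign, the exceptions being probes of YPEL4 and IRS2. Probe positions are those in the files, on hg18, and exon or untranslated region was not analysed here.

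The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05, two-sided. For a gene not well above background on any array of one group, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Gene lists, 28 in number and with at least 5 measured members, were tested with camera on the same fit at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives, and no call held with the estimated correlation. Markers of lung epithelium, mesenchyme and leukocytes were among the lists to look for other cell types, and lung epithelium was included in case the line has a hybrid parent, which the labels do not say. Data were handled with the R package data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9.

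The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Named were the 10 largest rises and the 10 largest falls among genes past the threshold with fully separated groups, up to 4 members with the lowest p of each list called by camera, up to 2 members past the threshold of every other list, and 16 genes chosen in advance, which were NR3C2, NR3C1, HSD11B2, FKBP5, PER1, SGK1, TSC22D3, ZBTB16, SCNN1A, ESM1, ANGPTL4, SIK1, ICAM1, VCAM1, EDN1 and NOS3. Features without a gene name were counted and not named. A symbol the files give in an older form is printed in its current form.

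The arrays lay on 2 slides, scanned apart. Slide 1 held the 3 untreated arrays and treated replicate 1, and slide 2 the other treated arrays. Values were therefore also computed with the slide as a block and within slide 1. Because slide 2 holds 1 group only, both give the same difference. The median signal of an array was between 105 and 121 units and the 75th percentile between 1115 and 1210 units, and the number of arrays limits the precision. The alternatives were other scalings, normexp background correction with an offset of 50, other filters, other probe rules, slide and replicate blocks, other eBayes settings, other thresholds, the deposited value table and leaving out each array in turn.

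The procedure was tested on simulated data with the spread and size of this comparison, 19683 features. Of 50 genes changed at each size, 20% were recovered at 1.5-fold, 82% at 2-fold and 98% at 4-fold and at 8-fold, with 7 calls among 19461 unchanged features. A list shifted by 0.5 was found by camera and 0 of the other lists were called. The simulated genes varied independently of each other, and no difference between slides was simulated. In the data the estimated correlation was 0.79 in the cell cycle G2/M list and 0.735 in the G1/S list. The simulation therefore does not show how many false calls correlated genes or the slides would give.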

Results

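Total RNA from MR-EAhy, a human endothelial cell line that the series title describes as expressing the mineralocorticoid receptor, was profiled on Agilent whole-genome arrays with 1 colour. The cells had been kept for 24 h in medium with 0.2% charcoal-treated serum and were then left untreated or given 1 nM aldosterone, the main natural ligand of that receptor, for 6 h. There were 3 arrays without aldosterone and 3 with it, and the only comparison the design gives is between these groups. It asks which transcripts aldosterone changes in endothelial cells that carry the receptor. Between 63.7% and 69.9% of the gene spots of an array were well above background, and 19683 features were tested, of which 13069 were named genes and 6614 were probes without a gene name. The number of arrays limits the precision of every value. All values are on the log2 scale, and each difference is aldosterone minus no aldosterone with its standard error from limma. Over all arrays n = 3 arrays per group. Differences within slide 1 or with the slide as a block compare 1 treated array with 3 untreated arrays. Those with an array left out have 1 array fewer in that group.

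Aldosterone was accompanied by higher signal of 115 features and lower signal of 58 at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 75 of the former and 42 of the latter were named genes. The largest rise was that of IGFBP1, a secreted protein that binds insulin-like growth factors. Its probe (hg18 chromosome 7, 45899491 to 45899550) was not well above background on any array without aldosterone and was at least 29.8-fold higher with it (adjusted p = 0.0133). SPRY1, an inhibitor of receptor tyrosine kinase signalling (probe at hg18 chromosome 4, 124543944 to 124544003), rose by 3.06 ± 0.28, which is 8.34-fold, with an adjusted p of 0.0231. SPINK13, a Kazal-type protease inhibitor, the ubiquitin ligase gene TRIM63 and the membrane transporter gene FLVCR2 were likewise not well above background in any untreated array and were at least 7.72-fold, 2.90-fold and 3.64-fold higher. ESM1, which encodes the endothelial proteoglycan endocan, rose 3.78-fold. TRIM63 and ESM1 were close to the threshold (limma adjusted p = 0.0479 and 0.047). MT1M, TMTC1, AKAP12, which encodes a scaffold protein for protein kinase A, and the transcription factor gene KLF9 rose between 3.17-fold and 3.31-fold.

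Falls were smaller, with 16 features lower by 2-fold or more against 65 that were higher by as much. ADGRB3, an adhesion G protein-coupled receptor gene (probe at hg18 chromosome 6, 70155587 to 70155646), fell by 1.75 ± 0.19 on the log2 scale, which is 3.36-fold, with an adjusted p of 0.0268. DPF3, which encodes a subunit of a chromatin remodelling complex, was 3.01-fold lower. ARL14, a small GTPase gene, was 2.91-fold lower (limma adjusted p = 0.0491), and UPB1, an enzyme gene of pyrimidine breakdown, 2.52-fold. CNIH3, PRSS35 and HAVCR2, which encodes the immune receptor TIM-3, were 2.40-fold, 2.39-fold and 2.18-fold lower. YPEL4 was 2.26-fold lower at its brighter probe, whereas its other probe differed by 0.33. TRAPPC3L and ATP6V1G3, a subunit gene of the vacuolar proton pump, were not well above background in any treated array, and were at least 1.11-fold and at least 1.88-fold lower.

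The 3 treated arrays lay on one side of the 3 untreated arrays for each of the 173 features past the threshold, and for 25.0% of all features tested. By chance 10% would be separated if the 6 arrays were exchangeable, and 25% if the arrays of slide 2 stood apart and only those of slide 1 were exchangeable, so this share does not tell treatment from slide. Treated replicate 1 shared slide 1 with the 3 untreated arrays, whereas treated replicates 2 and 3 were on slide 2. Within slide 1 the test of 1 treated against 3 untreated arrays called 1 feature. That full separation already fixes the sign of the 173 features within slide 1. With the slide as a block the difference is the same one, treated replicate 1 against the 3 untreated arrays. Slide 2 then adds only to the estimate of the spread, so the calls with this block also rest on 1 treated array. With the slide as a block 82 features were called, 60 higher and 22 lower, and 41 of the 173 were among them. Of the 35 genes past the threshold that the naming rule took, 12 were called with the slide as a block, namely IGFBP1, SPRY1, FLVCR2, TMTC1, KLF9, GADD45B, MAOA, ANGPTL4, DDIT4, DPF3, YPEL4 and TRAPPC3L. The other 23, among them FKBP5, PER1, ESM1 and ADGRB3, were not. The number of calls depended on single arrays: it was 0, 1 and 2 without untreated replicate 1, 2 and 3, and 2256, 32 and 0 without treated replicate 1, 2 and 3. The 1 call without untreated replicate 2 was among the 173, and the 2 without untreated replicate 3 were not. The 2256 included all 173, and the 32 included 30 of them. The counts of 0 from limma stood beside 2944 features with an unadjusted p under 0.05 without untreated replicate 1 and 2206 without treated replicate 3, against 3847 with all arrays. Without treated replicate 1, slide and group cannot be told apart. Scaling by the median gave 71 higher and 73 lower, and quantile normalization 109 higher and 87 lower.

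**Figure D1:**
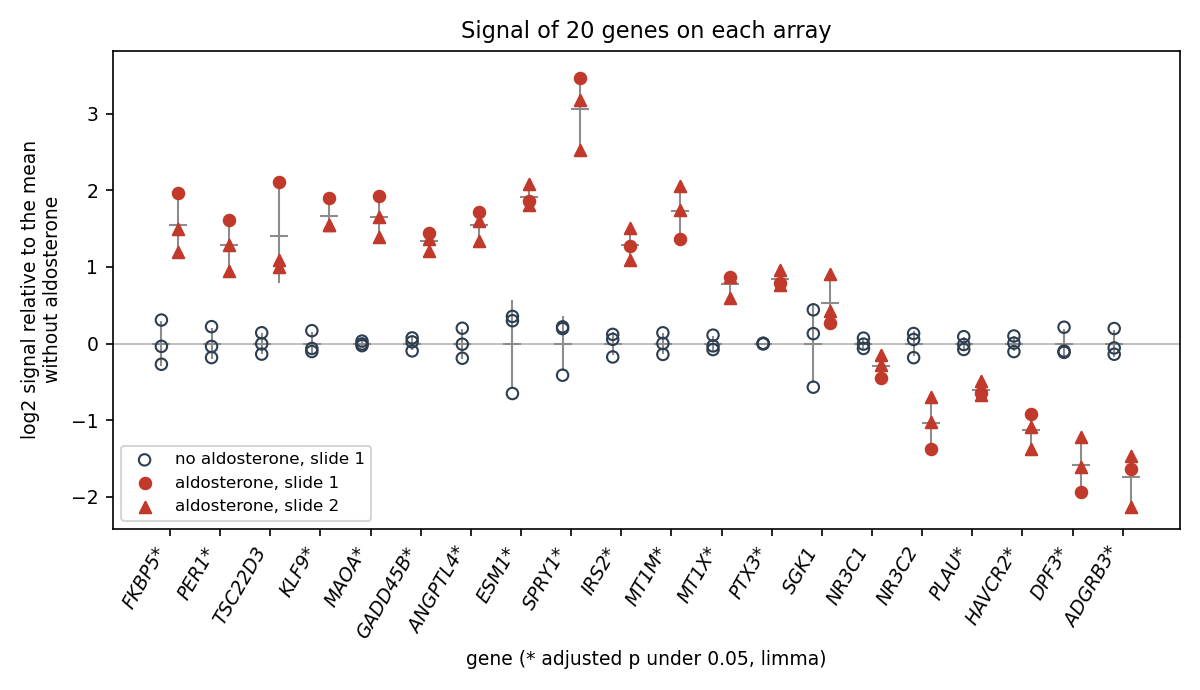
Log2 signal of named genes on each of the 6 arrays (vertical axis), relative to the mean of the 3 arrays without aldosterone, with open symbols for untreated and filled symbols for treated arrays, circles for slide 1 and triangles for slide 2. Bars show mean and SD (n = 3 per group). The 3 treated arrays of FKBP5, KLF9 and SPRY1 lie above the 3 untreated arrays, and those of SGK1 overlap them.

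Of the 34 measured members of the list of known corticosteroid receptor targets, which was fixed before the data were examined, 12 rose and none fell over all features tested, and 19 rose and 1 fell when adjusted over the list alone. FKBP5, a cochaperone of steroid receptors, rose by 1.55 ± 0.23, and the clock gene PER1 by 1.28 ± 0.19. Both were close to the threshold (limma adjusted p = 0.0491 for each), and each passed it in 12 of 23 settings, the main one included. KLF9 rose by 1.66 ± 0.13, MAOA, which encodes monoamine oxidase A, by 1.66 ± 0.14, and GADD45B, a stress-response gene, by 1.34 ± 0.10. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose 2.94-fold, and DDIT4, an inhibitor of mTORC1 signalling, 2.49-fold. The list's mean difference was 0.75, or 0.72 with IGFBP1 at its bound, and its median was 0.50. The mean was 0.84 both within slide 1 and with the slide as a block. The list was called by camera with a preset correlation (adjusted p = 7.3e-11), but not with an estimated correlation (adjusted p = 0.372).

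Other well-known corticosteroid targets did not pass the test for single genes over all arrays without a block. TSC22D3, which encodes the leucine zipper protein GILZ, differed by 1.40 ± 0.30 (limma adjusted p = 0.0935) and was higher in 3 of 3 treated arrays than in any untreated one. With the slide as a block it differed by 2.11 and was called (adjusted p = 0.0204), and without treated replicate 1 it differed by 1.05 and was also called. Its adjusted p ranged from 0.00461 to 0.281 over the alternatives. SGK1, the serum- and corticosteroid-regulated kinase gene, differed by 0.53 ± 0.29 and the transcription factor gene ZBTB16 by 0.48 ± 0.24, with adjusted p of 0.371 and 0.341 and overlapping arrays. SIK1, a salt-inducible kinase gene, differed by 0.24 ± 0.10 at its brightest probe (limma adjusted p = 0.255), but by 1.08 and 1.10 at the others, with fully separated groups at each. As the mean of its probes it differed by 0.81 and passed the threshold (adjusted p = 0.04, in a range of 0.04 to 0.879 over the alternatives).

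Metallothioneins, small metal-binding proteins, were higher with aldosterone. Of 10 measured members 5 rose and none fell over all features, and 9 rose when adjusted over the list alone. MT1M rose by 1.72 ± 0.18, and MT1E, MT1B and MT1X rose by 0.93, 0.83 and 0.78. The remaining member past the threshold was MT1G, at 0.76, which was named after its value was seen. The list's mean difference was 0.83, and it was 0.83 within slide 1 and with the slide as a block (camera adjusted p = 7.3e-11, and adjusted p = 0.372 with an estimated correlation). These genes are near-identical copies, so that signal may be shared between their probes and the values of single members are uncertain.

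In the insulin and growth factor signalling list, 5 of 21 measured members rose and none fell over all features, and 7 rose when adjusted over the list alone. The 5 were IGFBP1, SPRY1, IRS2, ERRFI1 and IGFBP3, the last of which was named after its value was seen. IGFBP1, IRS2 and ERRFI1 were also members of the corticosteroid target list. IGFBP1 and IGFBP3 encode proteins that bind insulin-like growth factors, SPRY1 and ERRFI1 inhibitors of receptor tyrosine kinases, and IRS2 an adaptor of the insulin receptor. ERRFI1 rose by 1.51 ± 0.19, IGFBP3 by 1.55 and IRS2 by 1.29 ± 0.14, although another IRS2 probe differed by -0.16. The mean over the list was 0.61, or 0.56 with IGFBP1 at its bound, the median was 0.24, and the mean within slide 1 and with the slide as a block was 0.67. The camera call (adjusted p = 0.00608) was lost with an estimated correlation (adjusted p = 0.372) and without treated replicate 1 (mean 0.58, adjusted p = 0.18). It was also lost with no filter on dim probes and with the replicate block, and the adjusted p ranged from 0.0011 to 0.372 over the alternatives.

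Lower means were found for interferon response and cell cycle genes, without a single member past the threshold in limma. In the interferon response list 6 of 26 measured members were lower at an unadjusted p under 0.05 and none higher. MX1, an antiviral GTPase gene, differed by -0.42, and OAS1, IFI44 and RIGI, which act in antiviral defence and sensing, by -0.38, -0.31 and -0.36. The list's mean was -0.18, it was -0.20 within slide 1 and with the slide as a block, and it was called by camera without the block (adjusted p = 0.00608) and with it (0.0119, in a range of 2.03e-05 to 0.971 over the alternatives) but not with an estimated correlation (adjusted p = 0.971). Without untreated replicate 3 the mean was -0.09 and the call was lost. The value within slide 1 rests on treated replicate 1, and untreated replicate 1 was at -0.15 relative to the untreated mean.

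The cell cycle G2/M list had a mean of -0.19 over 26 members, and the G1/S and DNA replication list one of -0.24 over 25, with 2 members each at an unadjusted p under 0.05, all lower. CDC20, an activator of the anaphase-promoting complex, differed by -0.38, the spindle genes CENPE, BUB1B and AURKA by -0.19, -0.43 and -0.28, the cyclin gene CCND1 by -0.49, and the replication genes MCM3, ORC1 and RFC4 by -0.54, -0.55 and -0.44. Both lists were called by camera (adjusted p = 0.00608 and 0.00857) and lost the call with an estimated correlation (adjusted p = 0.971 for both). Within slide 1 and with the slide as a block the means were 0.03 and 0.07, so the direction did not hold against the mean of the untreated arrays there. These values rest on treated replicate 1. Untreated replicate 1 on the same slide was higher, at 0.23 for G2/M and 0.275 for G1/S. Without untreated replicate 1 both calls were lost, at means of -0.08 and -0.10. The G2/M call was also lost without treated replicate 3 (mean -0.09), and the G1/S call without treated replicate 2 (mean -0.10).

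**Figure D2:**
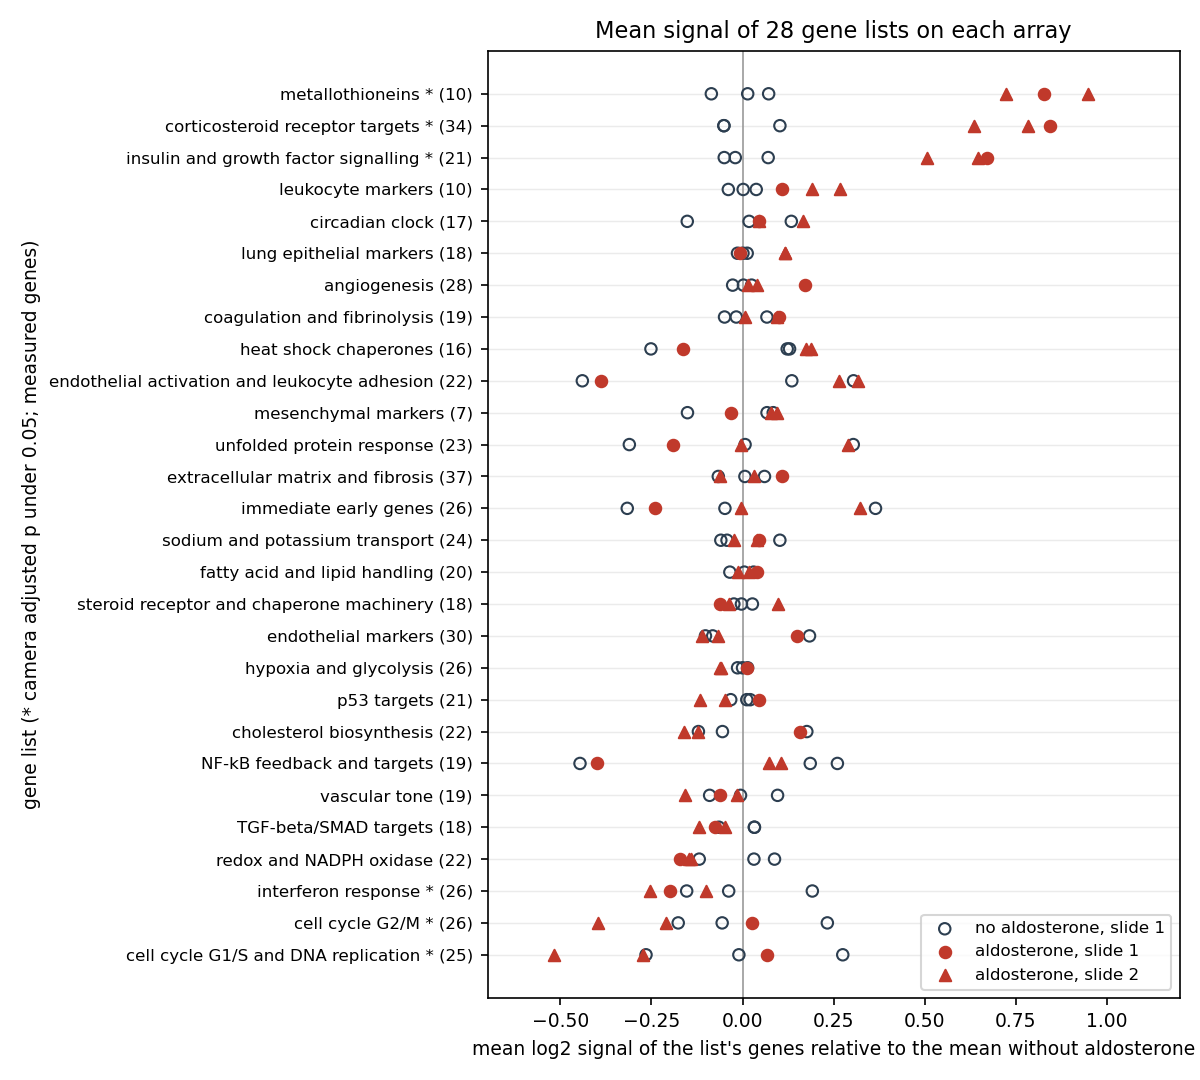
Mean log2 signal of each gene list on each array (horizontal axis), relative to the mean of the 3 arrays without aldosterone, with open symbols for untreated and filled symbols for treated arrays, circles for slide 1 and triangles for slide 2, and the number of measured genes in parentheses. The treated arrays lie between 0.64 and 0.84 for corticosteroid receptor targets, whereas in the NF-kB list untreated replicate 1 at -0.45 and treated replicate 1 at -0.40 lie apart from the other arrays.

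None of the other 22 lists was called (lowest camera adjusted p = 0.208), and their means lay between -0.15 and 0.19. Single members of lists on vessel biology nevertheless passed the test over all arrays, although ESM1, CALCRL, PLAU, PTX3 and KLF6 lost the call with the slide as a block. ESM1 and ANGPTL4 were the members of the angiogenesis list that rose. CALCRL, the receptor gene for adrenomedullin and calcitonin gene-related peptide, rose by 0.92 ± 0.13 in the vascular tone list, in which 7 of 19 measured members were lower and 1 higher at an unadjusted p under 0.05, and 1 fell when adjusted over the list alone. PLAU, the urokinase gene, fell by 0.61 ± 0.09 as a member of the coagulation and extracellular matrix lists. Its limma adjusted p, like that of KLF6, was 0.0491. PTX3, a secreted pattern recognition protein gene, rose by 0.84 ± 0.09 in the list of endothelial activation and leukocyte adhesion. KLF6 rose by 0.77 among immediate early genes, and the lists of circadian clock, lipid handling, unfolded protein response, heat shock and steroid receptor machinery each held 1 member that rose, which were PER1, ANGPTL4, DDIT4 and, for the last pair, FKBP5. In 9 of the 22 lists the mean lay above 0 and the median below it, with camera's direction up in 5 and down in 4.

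The endothelial activation and adhesion list had a mean of 0.06 over all arrays, and of -0.39 within slide 1 and with the slide as a block. For NF-kB feedback and targets the corresponding values were -0.07 and -0.40. With the slide as a block camera called both lists lower (adjusted p = 0.0439 and 0.00245, in ranges of 0.0439 to 0.998 and 0.000603 to 0.971 over the alternatives), and it called the NF-kB list lower without untreated replicate 1 as well (mean -0.30). These calls used the preset correlation of 0.01, whereas the correlation estimated over all arrays was 0.40 and 0.64 for the adhesion and NF-kB lists. The slide block rests on treated replicate 1, and untreated replicate 1 was as low, at -0.44 and -0.45 against -0.39 and -0.40 for the adhesion and NF-kB lists. ICAM1, an adhesion molecule gene, differed by -0.33 ± 0.31 (limma adjusted p = 0.606). VCAM1 was well above background on 1 untreated and 2 treated arrays and was not tested. EDN1, which encodes endothelin-1, differed by -0.02 ± 0.12, and NOS3, the endothelial nitric oxide synthase gene, by -0.32 ± 0.12, with adjusted p of 0.953 and 0.215.

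The receptor transcripts themselves were not past the threshold over all arrays. The probe of NR3C2, the mineralocorticoid receptor gene (hg18 chromosome 4, 149219814 to 149219873), had a mean of -1.23 ± 0.16 (SD) without aldosterone and -2.26 ± 0.34 with it, a difference of -1.03 ± 0.19 (limma adjusted p = 0.072) that was lower in 3 of 3 treated arrays and was -1.38 within slide 1. It passed the threshold with median scaling (-1.11), with normexp background correction (-0.92) and without treated replicate 1 (-0.86), and its adjusted p ranged from 0.0211 to 0.25 over the alternatives. Whether this probe lies in the part of the transcript carried by an introduced receptor is not given in the sources used here. NR3C1, the glucocorticoid receptor gene, differed by -0.30 ± 0.10 at its brighter probe and by -0.40 at the other (adjusted p = 0.201 for the former). HSD11B2, which encodes the enzyme that inactivates cortisol, was well above background on 3 untreated and 2 treated arrays and differed by 0.16 ± 0.21 (adjusted p = 0.718). SCNN1A, a subunit gene of the epithelial sodium channel, was not well above background on any array. In the sodium and potassium transport list 0 of 24 measured members passed the test in limma, 4 had an unadjusted p under 0.05, and the mean was 0.02, or 0.05 within slide 1. Adjusted over the list alone 1 member rose, CNKSR3, at 1.03 (adjusted p = 0.055 over all features), which was named after its value was seen.

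No cell type marker list was called by camera. Endothelial markers had a mean of -0.01 over 30 members, lung epithelial markers 0.07 over 18, mesenchymal markers 0.05 over 7 and leukocyte markers 0.19 over 10, and the means within slide 1 and with the slide as a block were 0.15, -0.01, -0.03 and 0.11. The leukocyte list's mean was higher on each treated array (0.11 to 0.27) than on any untreated array (-0.04 to 0.04). None of these members was past the threshold in limma, while 8, 8, 3 and 2 had an unadjusted p under 0.05. Adjusted over the list alone, 4 lung epithelial markers were higher and 4 lower, 1 endothelial marker and 1 leukocyte marker were higher, and no mesenchymal marker was called. Over all tested features, arrays of one group correlated at 0.989 to 0.997 and arrays of different groups at 0.982 to 0.992, and the arrays lay closer by slide than by group. Treated replicate 1 correlated at 0.991 to 0.992 with the untreated arrays of its slide and at 0.989 with both treated arrays of slide 2. On the first principal component, which held 55.0% of the variance, it lay at -7.38, nearer to the untreated arrays (-35.4 to -17.5) than to the treated arrays of slide 2 (37.3 and 41.8). These correlations are across genes, which are not independent replicates.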

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

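The alternatives were chosen before the data were examined. The 173 features past the threshold kept their sign under each alternative that measured them, which full separation of the groups fixes for subsets of the arrays, while the number of calls changed by more than 1.5 times under several, and the cause was not tested except as stated. Median scaling called 71 features higher. With no filter on dim probes, where 31068 features were tested, limma called 0 in total, 0 higher and 0 lower, beside 4954 at an unadjusted p under 0.05. The slide as a block gave 82 calls (60 higher, 22 lower), the slide as a random block 109 (30 lower), and slide 1 alone 1 (1 higher, 0 lower, and 2125 features at an unadjusted p under 0.05), where 1 treated array is assumed to vary like the untreated ones. An adjusted p under 0.1 gave 660 calls, 378 higher and 282 lower. Leaving out 1 array gave between 0 and 2256 calls, 0 to 1801 higher and 0 to 455 lower, and 5 to 6 of the gene lists. Of the 6 lists called by camera, 0 were called with an estimated correlation. By fry, which does not compare a list with other genes, 3 lists changed on balance in one direction and 16 in either direction. The 3 were metallothioneins, corticosteroid targets and insulin and growth factor signalling (fry adjusted p = 0.00762 for each). Interferon response (0.436) and the G2/M and G1/S lists (0.607 for both) were not called by fry in one direction. With the slide as a block and within slide 1, the G2/M mean was 0.0258, the G1/S mean 0.0667 and the endothelial activation and adhesion mean -0.3882, each with the opposite sign to that over all arrays. These are the lists called over all arrays or with the slide as a block whose sign changed. Lists without a call changed sign too, among them cholesterol biosynthesis (-0.04 to 0.16) and immediate early genes (0.03 to -0.24). The lists of corticosteroid targets and metallothioneins were called under each alternative except the estimated correlation, with means of 0.61 to 0.84 and 0.73 to 0.89. Where a gene was not well above background on any array of a group, the signal allowed only a bound on its fold. The replicate numbers were not taken to pair the arrays, because the labels do not say that they mark a shared culture or day. Deviations from the group means correlated at 0.39, -0.02 and 0.04 for numbers 1 to 3, and 2 of 6 arrays correlated best with their own number. Treated replicate 1 lay on another slide than treated replicates 2 and 3, so these values do not decide on pairing. The replicate block gave 87 calls (76 higher, 11 lower), 45 of them among the 173, and 5 lists, as did no filter on dim probes. In both the insulin and growth factor list was the one lost, at means of 0.61 and 0.62.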

Other observations

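All tests below except the splits of the arrays were chosen after the results they concern had been seen. Genes outside the rule for named genes also differed over all arrays without a block, and those given here were chosen after their values were seen. How they behaved with the slide as a block or with an array left out is not given here. Of the 35 genes past the threshold under the naming rule, 23 lost the call with the slide as a block. A pair of inositol trisphosphate receptor genes, which encode calcium release channels, moved apart: ITPR2 rose by 1.02 ± 0.07 and ITPR1 fell by 0.64 on the log2 scale. S1PR3, a receptor gene for sphingosine 1-phosphate, rose by 1.39, the chemokine gene CCL17 by 1.61 and CAVIN2, a caveola component gene, by 1.58. CCL17 was well above background on 1 of the 3 untreated arrays. NEDD9, an adhesion docking protein gene, rose by 1.64. NLRP3, an inflammasome sensor gene, fell by 0.82, E2F7, a repressor of cell cycle genes, by 0.95, FGF1, a growth factor gene, by 0.89 and KCNN3, a calcium-activated potassium channel gene, by 0.94.

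The 6 arrays can be split into 3 and 3 in 10 ways. The real split gave 173 features, and the highest of the other splits 0, so that 1 of the 10 splits, the real one, reached that number. With 10 splits the share cannot go below 0.1.

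The 6 lists called by camera were set against the slides. Within slide 1 the mean differences were 0.8269 for metallothioneins, 0.8434 for corticosteroid receptor targets and 0.6717 for insulin and growth factor signalling. All were over 2 SD of the untreated arrays' list means, which argues against a difference between slides as their whole cause. Each of these means rests on 1 treated array, and each SD on 3 arrays. Treated replicate 1 was also among the arrays that gave the calls, so the check is not independent of them. The insulin mean includes IGFBP1 at 6.38, not well above background on any untreated array, and SPRY1 at 3.47. The median of that list over all arrays was 0.24. The corticosteroid target list shares members with the others, among them MT1X, IGFBP1, IRS2 and ERRFI1, so the lists are not separate evidence. For the interferon response the slide block left the mean about as large and camera's call in place. That difference, -0.1982, rests on treated replicate 1 alone, and untreated replicate 1 on the same slide was at -0.1534. It also lay close to the spread of the untreated arrays (SD 0.1756), so the test did not decide whether the slides were the cause. The G2/M and G1/S lists differed within slide 1 by 0.0258 and 0.0667 from the untreated mean. Untreated replicate 1 was higher still, at 0.2327 and 0.275, so treated replicate 1 lay below it on the same slide. The lower means over all arrays thus depended on untreated replicate 1 as well as on slide 2. The difference within slide 1 also rests on 1 treated array, and the untreated list means had SDs of 0.21 and 0.27. A difference between the slides and an effect of aldosterone cannot be told apart for these lists.

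Leaving out treated replicate 1, the treated array on slide 1, raised the number of calls from 173 to 2256, 1801 of them higher. As a test, 1372 features were called from treated replicates 2 and 3 against untreated replicates 1 and 2 and then read on the remaining arrays, both on slide 1. Their median change there was 19.57% of the called change, with the same sign in 72.2%. A difference between the slides, or the samples on them, would give this. Selection for a large change would also give a smaller change on other arrays, and no reference for that was computed. The 1372 features are also not the same set as the added calls, so the test does not settle their cause. Of the features called higher, 48.92% lay in the dimmest 1/3 of those tested, so that a higher background on slide 2 may account for some of them, and this test did not decide it.

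Both arrays numbered 1 were low in inflammatory genes, whatever the treatment, and stood apart in other lists too, with means relative to the untreated group of -0.25 and -0.16 for heat shock chaperones and 0.18 and 0.15 for endothelial markers. Of the 41 genes in the adhesion and NF-kB lists, 31 were lower on both arrays than the mean of the other arrays of their group, and CXCL8, the interleukin-8 gene, was lower by 1.53 without aldosterone and by 1.91 with it. A difference between slides would not give the low values of untreated replicate 1, which lay below the other untreated arrays on the same slide. The differences in list mean were -0.6597 for adhesion and -0.67 for NF-kB. Treated replicate 1 differed from the other treated arrays by -0.68 and -0.49, but those lay on slide 2. For treated replicate 1 a difference between slides is thus not excluded. Weak hybridization was not decided: untreated replicate 1 had 68.13% of spots well above background, within the range of the arrays numbered 2 and 3, but treated replicate 1 had the lowest share (63.7%), and both had the lowest median signals, 105.41 and 105.49 against 111 to 121 units. Handling shared by the samples numbered 1 stays open too, as does a biological difference if the replicates were separate cultures. The labels do not say whether they were.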
